A study of Caenorhabditis elegans with 2 samples.

How the data were processed

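Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole hermaphrodite Caenorhabditis elegans larvae of the L3 stage, collected 36.5 h after release from a starved L1 synchronisation. Per the labels, the animals came from strain OP477, which carries an integrated transgene that expresses the nuclear hormone receptor NHR-43 with a C-terminal GFP-FLAG tag in an unc-119 mutant background, and an anti-GFP antibody was used. The antibody characteristic names nhr-43, the target, and was read as such. Chromatin was sheared by sonication. The 2 samples are biological replicates of 1 group, so the design holds no comparison between conditions. The labels list a control experiment. Its libraries were not analysed here.

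The deposited files are peak lists on the ce11 and ce10 builds. The authors deposited 1 relaxed list per replicate, 1 relaxed list from pooled reads and 1 thresholded list; per the file names, the relaxed lists were made as input for an irreproducible discovery rate (IDR) analysis. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the authors' own and its scale belongs to its list, so it served only to rank and describe peaks within a list. The −log10 q column was deposited by the authors with a ceiling, which all 3889 thresholded peaks reached at 2.69, so it was not used to rank peaks. The thresholded list was compared with the pooled list, and its 3889 peaks were the 3889 pooled peaks with the highest signal. Read depth per sample is not given in the sources used here, so no interval on a signal value was computed.

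The coordinates are those of the ce11 lists, which were used with the WBcel235 genome and the Ensembl release 115 annotation. No coordinate was converted between builds, and ce10 lists served only for counts and for overlaps among themselves. Coordinates are counted from 1. Peaks on mitochondrial DNA (19 of the thresholded list) were left out of the analyses of location, genes and motifs, which leaves 3870 nuclear peaks. Mitochondrial gene names were taken from the RefSeq annotation of the same assembly by position.

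Replicates were compared by the share of replicate 1's 3889 highest peaks whose summit lay within 100 bp of a summit among replicate 2's 3889 highest, against 1000 seeded random placements within chromosomes. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5' end of a protein-coding gene, and a gene with a thresholded summit in its window is called bound. The promoter share was tested against 1000 random placements with a two-sided permutation test, whose smallest possible p is 0.001. Shares of peaks on X and in the middle 50% of each autosome's length were tested against the shares of promoters there with two-sided exact binomial tests, and the 3 location tests were adjusted together. The 25 gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes. The 15 fixed motifs and all 2080 6-mers (both strands joined) were counted within 75 bp of each summit and in windows centred 500 bp to each side, with an exact McNemar test against 1 randomly chosen side. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Peaks and genes are not replicates: these p-values describe where peaks of this 1 data set lie.

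Relaxed peaks within 20 kb of the midpoints of nhr-43 and unc-119 were counted per replicate and ranked among 40 kb windows placed every 10000 bp. Genes are named by a rule set before the data were examined. It takes nhr-43, the genes with the nearest annotated 5' end to the 20 highest thresholded peaks, for each list past the test the 3 members with the highest promoter peaks, and the 10 6-mers with the smallest p. Because 18 of the 20 highest peaks proved to be mitochondrial, the 20 highest nuclear peaks were added after the values were seen. Other names given as the next members of a list, the comparison with reordered motifs, the noncoding gene classes, the motif comparison by class of peak and the word GCGCAGGG were also chosen then.

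The alternatives set before the data were examined were the highest-signal peaks alone, merged peaks, the 3889 highest peaks of each replicate alone, the ce10 lists, other summit distances, other promoter windows, assignment to the nearest 5' end within 2000 bp, other backgrounds and other motif windows. Leaving out peaks within 500 bp of a tRNA gene was added later. The scripts were tested on simulated data. In the gene list test on 19973 genes, a list with 30 planted peaks was called and 0 of 20 unplanted lists were. In the motif test on 3870 windows the planted motif was called, with 1 of the 14 other motifs, and the planted 6-mer ranked first. These windows lay at random positions, so the higher G+C content of real summits over their flanks was not simulated. In the overlap step 40.5% of peaks were found shared where 40.1% had been planted. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.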

Results

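NHR-43, a nuclear hormone receptor, was mapped by ChIP-seq of a GFP-tagged transgene product in L3 larvae, in 2 biological replicates. The thresholded list held 3889 peaks, of which 825 lay on X, 662 on II, 649 on V, 623 on III, 574 on IV, 537 on I and 19 on mitochondrial DNA. The relaxed lists held 29315 peaks for replicate 1 and 30000 for replicate 2. The most frequent peak width was 324 bp in the thresholded list, 276 bp in replicate 1 and 324 bp in replicate 2.

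The first comparison asks whether both replicates gave the same sites. Among the 3889 highest peaks of each replicate, 2000 (51.4%) had summits within 100 bp of each other, against a mean of 0.906% and a maximum of 1.39% in random placements (two-sided permutation p = 0.001, the smallest these allow). The placements were uniform within each chromosome and ignored promoters, where peaks were concentrated. They therefore do not separate shared NHR-43 sites from a shared preference of both replicates for such regions. The thresholded peaks come from the pooled reads of both replicates. Of them, 84.3% had a relaxed summit of replicate 1 within 100 bp, 92.4% had one of replicate 2, 78.1% had both and 1.29% had neither. The share of thresholded peaks with such a summit among a replicate's 3889 highest peaks was 64.1% for replicate 1 and 75.4% for replicate 2. No chance level was computed for these shares. Over the 3022 nuclear thresholded peaks found in both replicates, the signals were correlated across peaks with Spearman's rho of 0.645. The pooled peak at rpl-3, which encodes a protein of the large ribosomal subunit, had the highest signal of all nuclear peaks and ranked 19 in replicate 1 and 18 in replicate 2.

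**Figure D1:**
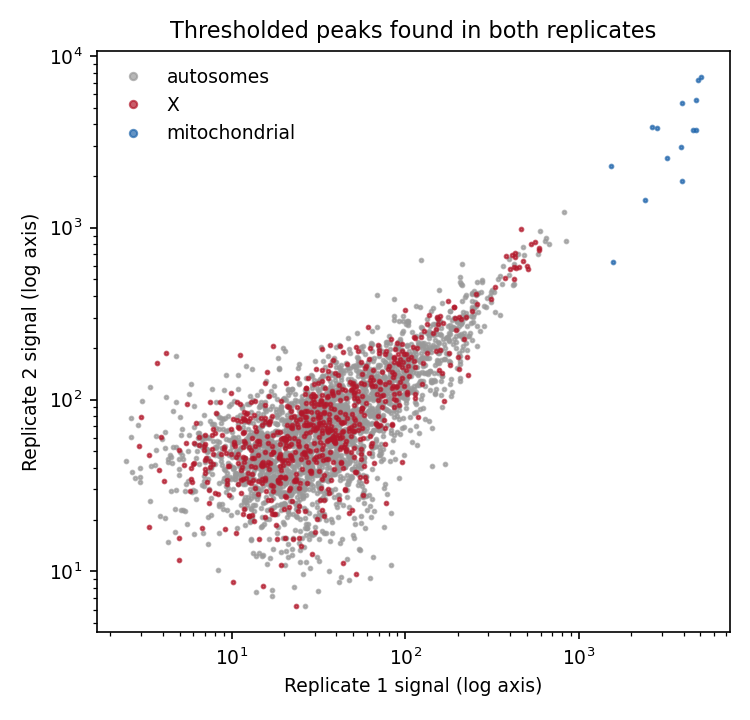
Signal of each thresholded peak in replicate 1 (x axis, log scale, the authors' units) against replicate 2 (y axis, log scale), for the peaks with a summit within 100 bp in both; colours mark autosomes, X and mitochondrial DNA. The nuclear peaks follow 1 trend with Spearman's rho of 0.645, and mitochondrial peaks lie at the upper right.

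The second comparison asks which sites and genes carry the strongest signal. By the naming rule, 18 of the 20 highest peaks were mitochondrial. The highest lay at position 12459, within ND5, with a signal of 12950.36, and the next at 10158, nearest to the 5' end of COX2, with 11847.44. The others were nearest to COX1, ATP6, CYTB, COX3, ND3, ND1, ND2, ND4L, ND4 and again COX2. The remaining 2 of the 20 were nuclear. One lay at III:3867413-3867726, 286 bp upstream of rpl-3 (WBGene00004414), with a signal of 2066.39. The other lay between genes at IV:9867889-9868421, 3066 bp downstream of the 5' end of K07F5.22, with 1724.02.

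The list of the 20 highest nuclear peaks was drawn up after the values were seen. It includes promoters of 4 ribosomal protein genes. Besides rpl-3, there are a peak 288 bp upstream of rpl-20 and 174 bp upstream of its divergent neighbour Y17G9B.5 (IV:4749931-4750220, signal 1553.4), a peak 460 bp upstream of rpl-35 (III:7854540-7854839, signal 1545.3) and a peak 354 bp upstream of rpl-15 (IV:654768-655085, signal 1302.37). Others lay 54 bp upstream of tasp-1, a threonine protease gene (III:10759078-10759420, signal 1579.19), 151 bp upstream of cdc-48.1, which encodes an AAA ATPase (II:10563428-10563705, signal 1213.79), and 236 bp upstream of sec-61.G, a subunit of the protein translocation channel (V:10897214-10897521, signal 1106.84). All of these summits lay between genes.

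A pair of nuclear hormone receptor genes is also among these 20. The peak nearest to nhr-21 lay between genes 1548 bp upstream of its 5' end (II:7337368-7337932, signal 1494.08). The peak nearest to nhr-14 lay in an intron, 879 bp downstream of the 5' end (X:8475080-8475515, signal 1097.87). On V, peaks in introns lay 9853 bp downstream of the 5' end of D2023.1 (11799084-11799774, signal 1293.36) and 9391 bp downstream of that of D2023.3 (11802451-11802852, signal 1124.1).

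Another 8 of these 20 peaks lay on X away from promoter windows. The highest was at X:6296275-6296901, in an intron and 3347 bp upstream of cest-16, with a signal of 1461.51. The next was at X:13700541-13701171, between genes, 6024 bp upstream of K02D3.1, with 1397.23. Other X sites lay nearest to W02H3.3, F55G7.5, F20B6.9, ZK899.6, F22H10.2 and F19H6.5, at distances of 1404 to 3977 bp downstream of the 5' end or, for F20B6.9, 1782 bp upstream. Their widths ran from 562 to 631 bp, against the most frequent width of 324 bp. At the summit near cest-16, the 51 bp from X:6296570 to 6296620 read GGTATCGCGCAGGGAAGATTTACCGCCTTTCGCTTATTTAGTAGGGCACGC. The 51 bp at the rpl-3 summit, III:3867543-3867593, read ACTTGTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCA.

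The third comparison places the peaks in the genome. Peaks were concentrated in promoters, on X and in the middle of autosomes. Of the 3870 nuclear summits, 1645 (42.5%) lay in a protein-coding promoter window, against 21.2% of random placements and at most 23.3% (two-sided permutation p = 0.001, adjusted p = 0.001 over 3 tests). Coding exons outside these windows held 8.19% of summits against 20.03% at random, and introns outside them 21.3% against 30.5%, while summits between genes outside them made up 21.5% against 21.9%. The permutation p was 0.001 for coding exons, 0.001 for introns and 0.524 for sites between genes.

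X held 825 of the 3870 nuclear peaks, or 21.3% (exact 95% interval 20.04 to 22.64%), against 13.7% of protein-coding promoters (exact binomial p = 1.74e-38, adjusted p = 2.61e-38). Against the X share of nuclear genome length, 17.7%, the exact binomial p was 6.58e-09. X had 46.6 peaks per Mb, close to 45.2 on III and 43.3 on II and above 31.02 on V. Peaks on X lay in promoter windows less often than autosomal ones, at 34.3% against 44.7% (Fisher's exact p = 6.45e-08), but promoter windows also cover less of X, at 17.6% of its length against 22.3% on autosomes. The share of peaks was thus 1.95 times the share of length on X and 2.01 times on autosomes, a difference that was not tested. On autosomes, 69.4% of 3045 peaks (67.8 to 71.1%) lay in the middle 50% of the length, where 55.7% of promoters lie (exact binomial p = 1.54e-54, adjusted p = 4.63e-54).

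The fourth comparison asks which protein-coding genes are bound. In all, 2010 of 19973 genes (10.1%) had a thresholded summit in the promoter window, and 10 of the 25 fixed lists differed from the other genes, 6 with a higher and 4 with a lower bound share. The control libraries were not analysed here, so a gene called bound is not thereby shown to be a target of NHR-43. Cytosolic ribosomal protein genes had the highest share, with 55 of 78 bound (70.5% against 9.83% of other genes, odds ratio 21.9, 95% interval 13.2 to 37.5, Fisher's exact adjusted p = 3.03e-36). Over the 9 alternatives the odds ratio ran from 6.11, with each peak given only to the nearest 5' end within 2000 bp, to 26.3, and it was 9.24 against genes with a relaxed pooled peak. Their highest peaks were at rpl-3, rpl-20 and rpl-35, and the next at rpl-15, rpl-12 and rpl-7A. Genes of the respiratory chain and ATP synthase followed, with 22 of 51 bound (43.1%, odds ratio 6.84, Fisher's exact adjusted p = 7.43e-09). Their highest peaks lay 281 bp upstream of cox-5A, a cytochrome c oxidase subunit (signal 887.4), 4 bp downstream of the 5' end of atp-1, an ATP synthase subunit (signal 415.2), and 272 bp upstream of atp-5 (signal 315.2). Their odds ratio ran from 4.19 to 7.84 over the alternatives.

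Heat shock proteins and chaperones had 19 of 59 members bound (32.2%, odds ratio 4.28, Fisher's exact adjusted p = 1.16e-05), led by the mitochondrial chaperonin gene hsp-60 (signal 949.2) and by cct-1 (716.9) and cct-8 (526.1), which encode subunits of the cytosolic chaperonin. With the nearest 5' end their odds ratio was 1.48 and the call was lost (Fisher's exact adjusted p = 0.403); it was 2.35 against genes with a relaxed pooled peak.

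Cell cycle and DNA replication genes had 8 of 27 bound (29.6%, odds ratio 3.77, Fisher's exact adjusted p = 0.0111). These were led by pcn-1, the sliding clamp of DNA polymerase (signal 342.4), cdc-6, a replication licensing factor (273.1), and lin-35, the retinoblastoma homologue (213.2). The call was lost in 3 of 9 alternatives, where the odds ratio was 3.67 with the highest-signal peaks, 2.35 with the nearest 5' end and 1.79 against genes with a relaxed pooled peak (Fisher's exact adjusted p = 0.0669, 0.162 and 0.412). Histone genes had 16 of 72 bound (22.2%, odds ratio 2.57, Fisher's exact adjusted p = 0.00718), led by his-37 (signal 809.0) and by his-67 and his-68, which share 1 peak (427.6). Epidermis and molting genes had 11 of 39 bound (28.2%, odds ratio 3.52, Fisher's exact adjusted p = 0.00435). Their highest peaks were at myrf-1 (signal 175.2), noah-1, an apical extracellular matrix gene (170.6), and nhr-25, another nuclear hormone receptor (96.6), whose peak had no partner within 100 bp in replicate 1. The epidermis call was lost in 4 of 9 alternatives, with odds ratios of 0.869 for the highest-signal peaks, 1.67 for replicate 1's highest peaks alone, 2.19 for the narrower promoter window and 1.59 against genes with a relaxed pooled peak, and was 7.10 with the nearest 5' end. The histone call was lost in 3 of 9, with 1.74 for the highest-signal peaks, 1.66 for replicate 1 alone and 1.33 with the nearest 5' end, and was 4.40 against genes with a relaxed pooled peak.

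4 lists were bound less often than other genes. Chemoreceptor genes had 16 of 1310 bound (1.22% against 10.7% of other genes, odds ratio 0.103, Fisher's exact adjusted p = 7.67e-40), the highest being sre-23 (signal 455.9), srh-17 (300.6) and srh-76 (221.2). F-box and MATH genes had 9 of 395 (2.28%, odds ratio 0.205, Fisher's exact adjusted p = 1.11e-08), led by fbxb-72 (signal 632.8), fbxb-85 (495.2) and math-33 (183.9). Immune effectors and lectins had 8 of 356 (2.25%, odds ratio 0.202, Fisher's exact adjusted p = 5.83e-08), led by spp-13 (signal 159.1), fipr-17 (147.7) and clec-53 (127.5). The list named for major sperm proteins, which also takes in genes named ssp, nspd and nspc, had 1 of 71 (1.41%, odds ratio 0.127, Fisher's exact adjusted p = 0.0223). That gene was nspc-17, not a major sperm protein gene by name, 767 bp from an X peak with a signal of 1045.82. Over the 9 alternatives the odds ratios ran from 0.0690 to 0.260 for chemoreceptors, 0.121 to 0.385 for F-box and MATH genes and 0.134 to 0.333 for immune effectors, with no call lost. The major sperm protein call was lost in 3 of 9 alternatives, with odds ratios of 0.229, 0.362 and 0.409.

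Nuclear hormone receptor genes were bound at the level of other genes, with 27 of 274 (9.85%, odds ratio 0.977, 95% interval 0.629 to 1.46, Fisher's exact adjusted p = 1). Their highest promoter peaks were at nhr-68 (signal 1035.62), nhr-43 itself (659.2), nhr-119 (367.4) and nhr-35 (359.7). Heterochronic pathway genes had 4 of 12 bound, lin-14, lin-66, lin-28 and lin-46 (33.3%, odds ratio 4.47, Fisher's exact adjusted p = 0.0594). With assignment to the nearest 5' end within 2000 bp their odds ratio was 16.5 (Fisher's exact adjusted p = 1.94e-05), the highest of the 9 alternatives, and the lowest were 2.40 in the narrower promoter window and 2.46 against genes with a relaxed pooled peak (Fisher's exact adjusted p = 0.366 and 0.412). Lipid metabolism genes had 22 of 138 bound, among them cpt-2, acs-2 and fasn-1 (15.9%, odds ratio 1.70, Fisher's exact adjusted p = 0.0657), and 2.72 under the nearest 5' end (Fisher's exact adjusted p = 1.2e-05) but 0.900 against genes with a relaxed pooled peak (Fisher's exact adjusted p = 0.851). Cuticle collagens had 23 of 174 bound (13.2%, Fisher's exact adjusted p = 0.256), and 2.01 was their odds ratio under the nearest 5' end (Fisher's exact adjusted p = 0.0022), against 0.958 with the relaxed pooled background (Fisher's exact adjusted p = 0.986).

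None of the 27 intestine genes and none of the 16 pharynx genes was bound, with upper 95% limits on the odds ratio of 1.31 and 2.32 (Fisher's exact adjusted p = 0.175 and 0.496). Body wall muscle had 1 of 35 bound (unc-112), neurons 2 of 36 (ric-19 and snb-1), vulva and Notch/Wnt signalling 1 of 34 (egl-17), germline 4 of 46 (nos-3, mes-2, cgh-1 and oma-2) and homeobox genes 3 of 87 (ceh-38, ceh-20 and ceh-74), and these were not past the test. Neuropeptides (7 of 140), xenobiotic metabolism (16 of 218), hedgehog-related and patched-related genes (9 of 87) and other transcription factors (14 of 148) were not past it either. With replicate 2's highest peaks alone, homeobox genes (odds ratio 0.223) and xenobiotic metabolism (0.454) were past the test (Fisher's exact adjusted p = 0.0363 and 0.0314). Members outside the leading 3 were named after their values were seen.

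**Figure D2:**
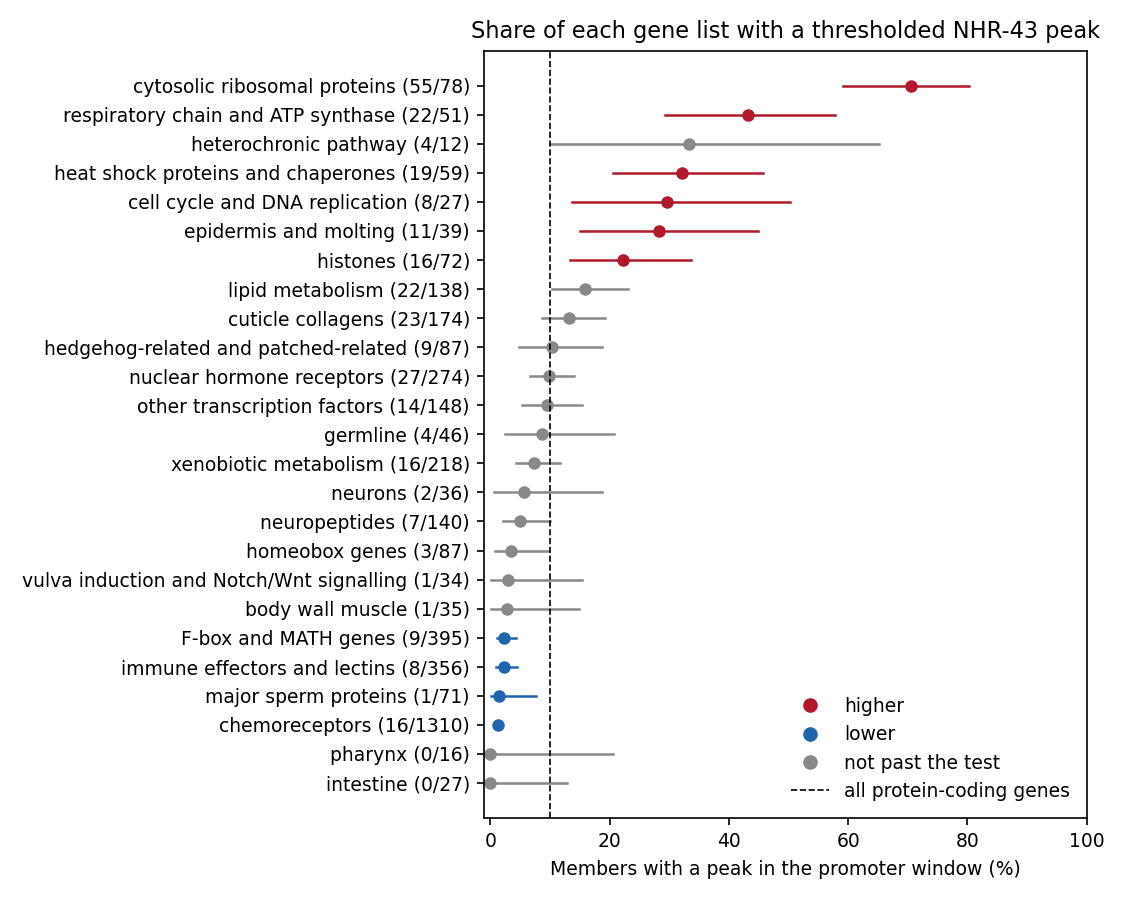
Percentage of each gene list's members with a thresholded summit in the promoter window (points, with exact 95% intervals as lines), with the number bound and the list size beside each name; the dashed line is the share over all protein-coding genes, 10.1%. Ribosomal protein genes lie at 70.5% and chemoreceptors at 1.22%.

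The fifth comparison asks which sequences mark the summits. GAGAGA, the GAGA-type motif, occurred within 75 bp of 1039 of 3870 summits (26.8%, exact 95% interval 25.5 to 28.3%), against 8.88% of flanking windows, a ratio of 3.02 (exact McNemar adjusted p = 9.38e-97). CTGCGTCTC, which resembles the site of the zinc finger factor EOR-1, occurred at 261 summits (6.74%, 5.97 to 7.58%) against 0.568% of flanks, a ratio of 11.9 (exact McNemar adjusted p = 5.43e-55), which ran from 7.58 in windows of 150 bp to each side to 15.5 over the 8 alternatives. The Sp1-type word CCGCCC occurred at 7.26% against 2.71% (ratio 2.68, exact McNemar adjusted p = 3.85e-20). Summit windows were richer in G+C than their flanks, at 43.2% ± 7.06 against 36.2% ± 5.99 (SD over 3870 peaks).

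Other orders of the same bases were then compared. GAGAGA exceeded all 19 other orders of its bases, whose median ratio was 1.37 and whose highest was 2.87. These orders include AGAGAG, which is the same repeat shifted along. For CTGCGTCTC, 4 of 284 sampled orders with a measurable ratio reached as high, with a median of 2 and a highest ratio of 42. For CCGCCC, 3 of the 5 other orders reached as high, and their median was 2.79.

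Words known as nuclear receptor sites were tested as well. The receptor core AGGTCA occurred at 5.71% of summits against 4.26% of flanks (ratio 1.34, exact McNemar adjusted p = 0.00365), with ratios of 1.27 to 1.57 and calls in all 8 alternatives, and its variant AGTTCA at 7.91% against 10.4% (ratio 0.757, exact McNemar adjusted p = 0.000766). For AGGTCA, other orders of the bases were not compared. Summit windows were richer in G+C, and 773 of all 2080 6-mers were also more frequent at summits. Whether this small ratio is specific to receptor sites is therefore left open. The extended site TCAAGGTCA occurred at 4 summits (0.103%, exact McNemar adjusted p = 0.737) and the direct repeat pattern at 0, which allows a share of up to 0.0953% (exact 95% limit). The HNF4-like CAAAGTCCA occurred at 9 summits (0.233% against 0.0904%, ratio 2.57, exact McNemar adjusted p = 0.0322), and this call was lost in each alternative that was run. TATAAA was less frequent at summits, at 10.1% against 16.6% (ratio 0.607, exact McNemar adjusted p = 4.37e-16).

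Small ratios above 1 were past the test for the GATA site TGATAA (1.16, exact McNemar adjusted p = 0.0132), the SKN-1 core RTCAT (1.08, exact McNemar adjusted p = 0.00365) and the BLMP-1-like TTTCACTT (1.35, exact McNemar adjusted p = 0.0132). With replicate 1's highest peaks alone, these ratios were 1.07, 1.05 and 1.01 and the calls were lost, as they were in 2, 4 and 4 of the 8 alternatives in all. The E-box CAGGTG (1.24), the forkhead site GTAAACA (1.33) and the AP-1 site TGACTCA (1.11) were not past the test (exact McNemar adjusted p = 0.0618, 0.255 and 0.616), although the forkhead ratio was 1.6 with replicate 2's highest peaks alone (exact McNemar adjusted p = 0.00124) and 0.921 with replicate 1's.

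Of 2080 6-mers, 773 were more frequent at summits and 468 less frequent. Of the 10 with the smallest p, GAGAGA, CGTCTC, AGAGAC, ACGCAG and AGAGAG were more frequent at summits and AAAATT, AAAAAT, TTAAAA, TAAAAA and AAATTA less frequent. AAAATT, which had the smallest p, occurred in 26.5% of summit windows and 51.3% of flanks (ratio 0.516, exact McNemar adjusted p = 4.05e-105). The 6-mer ACGCAG occurred in 14.2% of summit windows and 2.95% of flanks (ratio 4.82, exact McNemar adjusted p = 2.38e-71), and CGTCTC in 17.4% and 4.55% (ratio 3.84, exact McNemar adjusted p = 2.31e-75). All 10 were past the test in the same direction with random positions at the same distance from a 5' end as background, where 859 6-mers were higher.

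**Figure D3:**
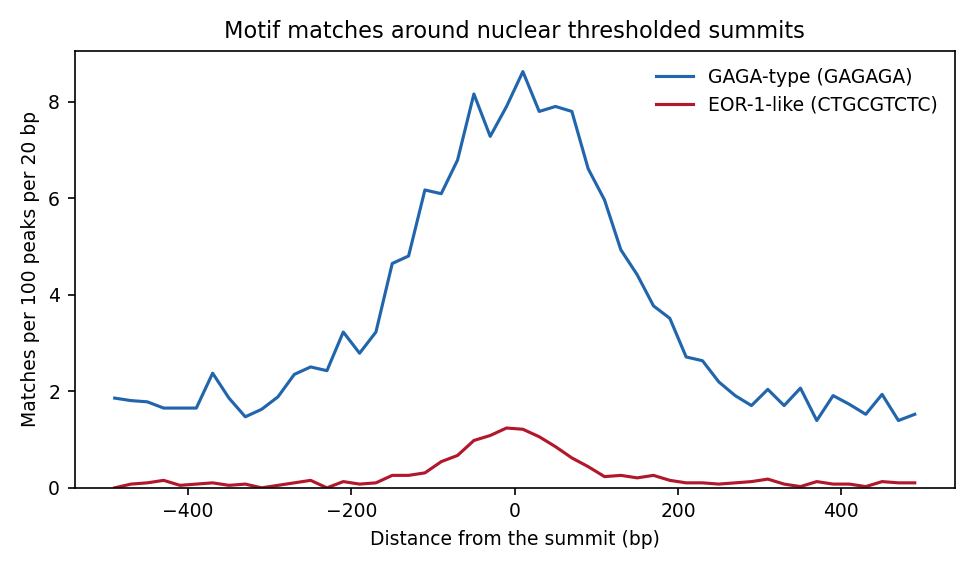
Matches per 100 nuclear thresholded peaks in 20 bp bins (y axis) by distance from the summit in bp (x axis), for GAGAGA and CTGCGTCTC on either strand. Both profiles are highest at the summit, where GAGAGA was found within 75 bp of 26.8% of peaks and CTGCGTCTC of 6.74%.

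The last comparison concerns the nhr-43 gene, whose product was tagged. The gene (WBGene00003633) lies at IV:11899590-11902976 on the plus strand, and 8 thresholded summits lay between 1656 bp upstream and 4255 bp downstream of its 5' end. The highest was 30 bp downstream of the 5' end, in an untranslated exon (IV:11899317-11899800), with a signal of 659.2 and ranks of 74 in replicate 1 and 75 in replicate 2. The next lay in an intron at IV:11901174-11901565 (signal 416.8) and between genes at IV:11897793-11898098 (signal 385.2). Replicate 1 had 7 of the 8 summits within 100 bp and replicate 2 all 8.

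Within 20 kb of the midpoint of nhr-43, replicate 1 had 33 relaxed peaks and replicate 2 had 40, against a median of 11 per 40 kb window in each. These counts lay at percentiles 99.1 and 99.6 of 10006 windows. At unc-119 (III:10902641-10908935), the gene mutated in the strain, the counts were 3 and 0, at percentiles 12.9 and 5.22. The transgene adds copies of nhr-43, so peaks at this gene can come from the transgene, from the chromosome or from both.

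**Figure D4:**
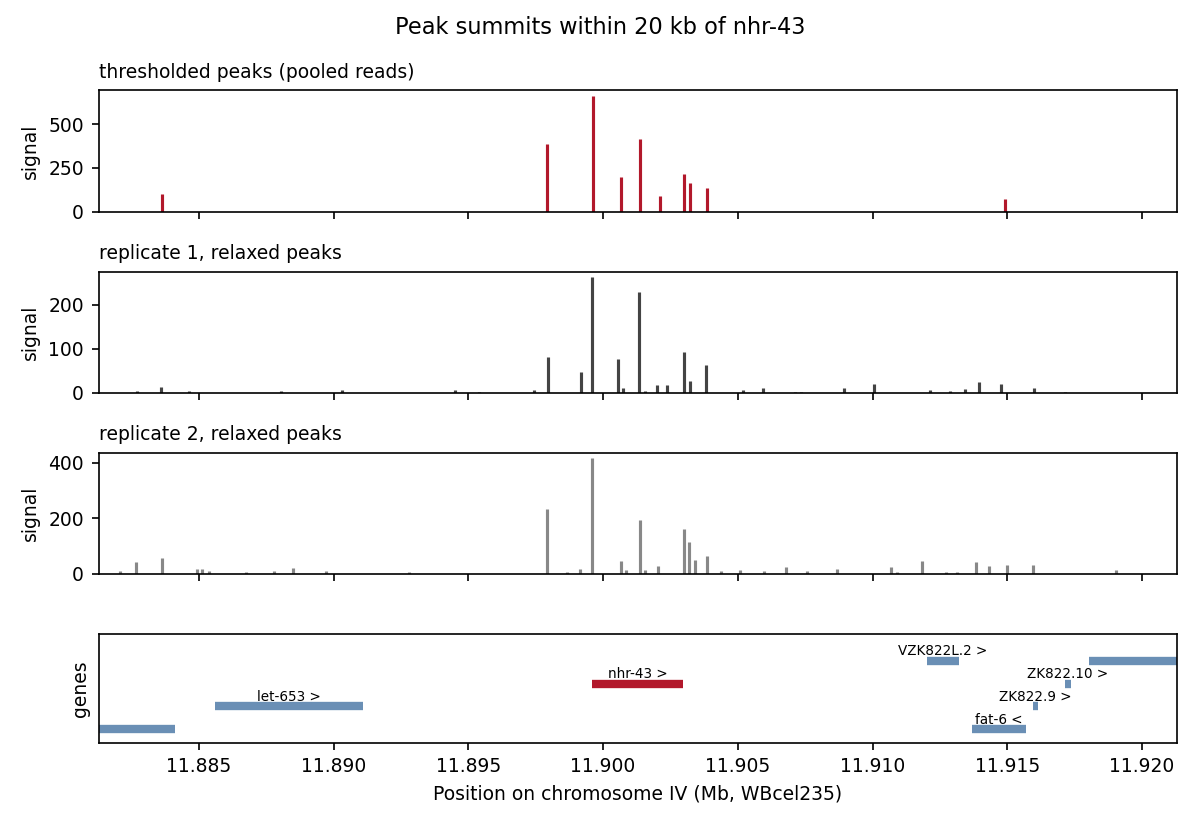
Summits within 20 kb of the midpoint of nhr-43 on chromosome IV (x axis, Mb), drawn as lines of height equal to the authors' signal for the thresholded list and for each replicate's relaxed list, with protein-coding genes below (arrows give the strand). Thresholded summits cluster from 1656 bp upstream to 4255 bp downstream of the 5' end, where 8 lie, the highest at 659.2.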

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

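A signal outside the comparisons of location, genes and motifs came from mitochondrial DNA. The thresholded list held 19 peaks there. They merged into 12 regions that cover 52.1% of the 13794 bp mitochondrial genome, and their signals ran from 1002.28 to 12950.36, against 2066.39 for the highest nuclear peak. Replicate 1 had 18 relaxed mitochondrial peaks and replicate 2 had 21. The control libraries were not analysed here, so no background level was available, and no explanation of these peaks was tested.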

How the results depend on the processing

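Leaving out peaks at tRNA genes was chosen after seeing the data; the other alternatives were set before. The promoter, X and autosome centre shares, the replicate overlap, the peak count, the number of enriched 6-mers and the nhr-43 percentile kept their direction and call under each alternative run, with counts within 1.5 times. Over all results 329 values kept both, 31 kept their direction but lost a call, 15 gained 1, 23 changed direction and 5 moved. Of the 23, only epidermis and molting with the highest-signal peaks had a call to lose. No paired analysis was possible because there is 1 group. Read depth was not available to set limits. The cause was not tested for any change below.

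With the highest-signal peaks (1925 nuclear peaks), 6 lists were past the test and 1169 genes were bound, and fewer peaks alone can lower both. Odds ratios were then 1.56 for other transcription factors, 0.981 for cuticle collagens, 0.869 for epidermis and molting, 0.774 for hedgehog-related genes and 1.53 for germline genes (changed direction), and 1.74 for histones, 3.67 for cell cycle genes and 0.229 for major sperm proteins (calls lost). Motif ratios were 0.667 for the extended monomer site (changed direction), and 2 for the HNF4-like core, 1.12 for GATA and 1.06 for the SKN-1 core (calls lost).

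With 1 replicate's highest peaks alone, 6 to 9 motifs were past the test. Odds ratios ran from 1.67 to 2.86 for epidermis and molting, 0.560 to 1.38 for hedgehog-related genes, 3.17 to 6.58 for the heterochronic pathway, 1.66 to 2.10 for histones, 0.223 to 0.560 for homeobox genes, 0.954 to 1.18 for nuclear hormone receptors, 1.04 to 1.15 for other transcription factors and 0.454 to 0.877 for xenobiotic metabolism. Motif ratios ran from 1.01 to 1.26 for BLMP-1-like, 1.07 to 1.15 for GATA, 1.17 to 2.5 for HNF4-like, 1.05 to 1.06 for SKN-1, 0.991 to 1.17 for AP-1 and 0.921 to 1.6 for forkhead sites. Replicate 2's peaks alone gained calls for homeobox genes (0.223), xenobiotic metabolism (0.454) and forkhead sites (1.6), and lost those for HNF4-like and BLMP-1-like words. Replicate 1's alone gained 1 for the heterochronic pathway (6.58), and lost those for epidermis and molting, histones, and HNF4-like, GATA, SKN-1 and BLMP-1-like words. Direction changed in both for other transcription factors, and with replicate 1's alone for hedgehog-related genes, nuclear hormone receptors, AP-1 and forkhead sites.

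Without peaks at tRNA genes the odds ratios were 0.937 for hedgehog-related genes (changed direction), and 1.76 for lipid metabolism and 4.64 for the heterochronic pathway (calls gained), and the HNF4-like ratio of 2.57 lost its call, as it did with merged peaks (2.57), where the E-box gained 1 (1.22). The narrower promoter window gave 2.19 for epidermis and molting (call lost). The wider one gave 0.383 for homeobox genes, 1.83 for cuticle collagens, 1.99 for lipid metabolism and 8.84 for the heterochronic pathway (calls gained).

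With the nearest 5' end, odds ratios were 1.33 for nuclear hormone receptors and 1.44 for other transcription factors (changed direction), 2.01 for cuticle collagens, 2.72 for lipid metabolism and 16.5 for the heterochronic pathway (calls gained), and 1.33 for histones, 1.48 for chaperones, 2.35 for cell cycle genes and 0.362 for major sperm proteins (calls lost). Against genes with a relaxed pooled peak, they were 1.04 for nuclear hormone receptors, 0.958 for cuticle collagens, 0.613 for hedgehog-related genes and 0.900 for lipid metabolism (changed direction), and 1.59 for epidermis and molting, 1.79 for cell cycle genes and 0.409 for major sperm proteins (calls lost).

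Motif windows of 50 bp to each side gave 0.4 for the extended monomer site (changed direction), and 2 for HNF4-like and 1.04 for BLMP-1-like words (calls lost). Windows of 150 bp gave 2 for the extended site (call gained), 0.99 for AP-1 (changed direction), and 2 for HNF4-like, 1.03 for SKN-1 and 1.11 for BLMP-1-like words (calls lost). Against random positions near 5' ends the ratios were 0.8 for the extended site and 0.836 for AP-1 (changed direction), and 1.8 for HNF4-like and 1.03 for SKN-1 words (calls lost). The unc-119 percentile was 18.1 with 10 kb to each side and 20.8 with thresholded peaks.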

Other observations

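The comparisons of noncoding genes, of motifs by class of peak, of words at ribosomal protein promoters, of the GCGCAGGG word and of the neighbours of nhr-43 were chosen after the peaks had been seen. Genes for tRNAs, snoRNAs and snRNAs often had a thresholded summit within 200 bp of the annotated 5' end. This held for 272 of 612 tRNA genes (44.4%, exact 95% interval 40.5 to 48.5%), 86 of 346 snoRNA genes (24.9%, 20.4 to 29.8%) and 25 of 129 snRNA genes (19.4%, 13.0 to 27.3%). Random placements of the peaks gave means of 1.64%, 1.58% and 1.30%, and at most 3.92%, 2.89% and 3.88% in 100 placements. The highest peaks of replicate 1 alone reached 37.3% of tRNA genes and those of replicate 2 reached 43.8%. piRNA genes had 41 of 15363 (0.267%, against 1.33% at random), pseudogenes 11 of 2128 (0.517% against 1.47%) and miRNA genes 7 of 261 (2.68%, against 1.70% and at most 4.21% at random; 5.36% and 4.21% with the highest peaks of replicates 1 and 2 alone). lincRNA genes had 15 of 194 (7.73%, against 1.68% and at most 5.15% at random; 4.64% and 5.67% with replicates 1 and 2 alone) and rRNA genes 0 of 20 (exact upper limit 16.8%). The miRNA and lincRNA shares are left open, since the thresholded list and the replicates alone differed in whether they exceeded the highest random value.

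CTGCGTCTC, GAGAGA, CCGCCC and GGTTCGA, the B box core, were compared between classes of site. CTGCGTCTC occurred at 9.41% of the 967 nuclear peaks with the highest signal and at 4.34% of the 967 with the lowest (Fisher's exact adjusted p = 5.29e-05 over 20 tests). It was more frequent at promoter windows, at 7.90% against 5.89% elsewhere (Fisher's exact adjusted p = 0.0296), and less frequent on X, at 4.12% against 7.45% elsewhere (Fisher's exact adjusted p = 0.00154), and at tRNA genes, at 1.205% against 7.13% (Fisher's exact adjusted p = 0.000124). At ribosomal protein promoters it occurred in 3 of 53 peaks (5.66%, interval 1.18 to 15.7%), which did not differ from other peaks past the test (Fisher's exact adjusted p = 1). GAGAGA was also more frequent at the 967 highest peaks, at 31.1% against 21.3% (Fisher's exact adjusted p = 7.42e-06). Its share was not past the test for promoters, X, ribosomal protein promoters or tRNA genes (Fisher's exact adjusted p = 0.266, 0.312, 0.631 and 0.0530). GGTTCGA occurred at 41.4% of peaks at tRNA genes against 1.55% elsewhere (Fisher's exact adjusted p = 1.16e-89). On X its share was 7.64% against 3.15% (Fisher's exact adjusted p = 8.96e-07). At promoters it was 2.98% against 4.94% (Fisher's exact adjusted p = 0.00533). For ribosomal protein promoters and the 967 highest peaks GGTTCGA was not past the test. The word TACCGTA, picked from these windows, occurred in 16 of the 52 peaks that are the highest of a ribosomal protein promoter (30.8%), in no flanking window and in 3.39% of 1593 other promoter peaks (Fisher's exact p = 6.37e-11, which is too small because the word was picked here).

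X held 20 of the 50 highest nuclear peaks in the thresholded list, and 20 of 50 in each replicate alone. Of these 20, 55% had GCGCAGGG, a word like the recruitment element of the X chromosome dosage compensation complex, within 150 bp of the summit, against 1.24% of 805 other X peaks (Fisher's exact p = 1.89e-14, which is too small because the word was chosen after these peaks were seen) and 0 of the 30 autosomal peaks among the 50. Repeated sequence is argued against for these 20 sites, since the median share of their 31-mers found more than once in the genome was 0%. Against the share of promoters, the wider excess on X did not rest on these sites alone or on tRNA genes alone. The X share was 20.9% without peaks that carry the word and 18.999% without peaks near tRNA genes. Both were above the 13.7% of promoters (exact binomial p = 8.44e-35 and 6.29e-19). Peaks of both kinds were not left out together, so their joint part in the excess was not tested. In a test added after these values were seen, the share without peaks near tRNA genes was only just above the 17.7% of nuclear genome length (interval 17.73 to 20.3%, exact binomial p = 0.0383), and 138 of those 254 peaks were on X; no biological explanation was tested, and the control libraries were not analysed here.

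Peaks at tRNA genes were weighed in the same way. A high G+C content is argued against, because tRNA genes exceeded positions between genes with matched G+C content by 41.2 percentage points (44.3% against 3.10%, with summits within 200 bp of the middle of the gene instead of its 5' end). Reads shared between tRNA copies remain possible. Only 9.09% of the 22 tRNA genes with no repeated 31-mer were bound (exact interval 1.12 to 29.2%), against 45.8% of the 590 others (Fisher's exact p = 0.000635). The 22 may also include diverged copies that are not transcribed, which was not tested, and no biological explanation was tested.

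The dense peaks at nhr-43 may come from extra transgene copies. Extra copies of both nhr-43 and the worm unc-119 gene were predicted to give high peak counts at both. The lowest of the 4 percentiles was 5.22, at unc-119 in replicate 2, so the prediction was not met. Such copies are not excluded by this, since peak counts do not measure copy number and a marker from another species would not show there. Extra copies of a segment that takes in the neighbours of nhr-43 cannot be told apart from other causes, because the lower of the 2 replicates' percentiles for relaxed peaks 5 to 20 kb from the midpoint, 91.8 in replicate 1, lay between the bounds set for a decision, while 96.8 in replicate 2 lay above both. The thresholded list had 2 peaks in these flanks (percentile 78.1), and the bounds were not set for that list. Binding of NHR-43 at its own gene was not tested, since the reads of both copies map to the same place.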
